A study of Mus musculus with 6 samples.

How the data were processed

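The deposited table holds 1 log2 expression value per probeset and array, 41345 probesets on 6 Mouse Gene ST arrays. Per the submitters' processing notes, Partek 6.6 and RMA were used, with no roles or settings; RMA background-corrects, normalizes and summarizes probes on the log2 scale. Per the labels' protocols, RNA was released from 10 blastocysts by heating in water and labelled with biotin, so input was low. The genome build is not given in the sources used here, and no coordinates are printed. The deposited log2 values lay between 1.52 and 14.2, with medians of 4.62 to 4.87. No detection calls were used here, so a level below the array's median is treated as dim, and folds against a dim group may be compressed.

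Groups and replicate numbers were taken from the sample titles. Probesets were named through the platform's annotation table, and symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probesets, 23521 had 1 symbol, 1814 had several and 16010 are not named here; 193 identifiers were not matched. Probesets with 1 symbol were kept where at least 2 of the 6 arrays were at or above the array's median, and the brightest probeset stood for its gene, which left 14020 genes. For Acss1, Eif4a1, Tdpoz2, Tmed10 and Uchl1, whose other probesets went otherwise or moved much less, those are given in the text.

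All 6 arrays were fitted together in limma 3.58.1 (R 4.3.3), with 1 mean per group, no block, and eBayes without trend or robust options, so that the 3 groups share 1 estimate of the spread (3 residual degrees of freedom and 2.81 prior degrees of freedom). Changes are differences of group means on the log2 scale, given with limma's moderated SE. p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05.

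Before the data were examined, 40 gene lists were fixed, covering the let-7 family and its targets, growth and protein synthesis, the cell cycle, metabolism, stress, embryonic lineages, and markers of oocytes, uterus and blood. Those 37 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 111 tests of 3 comparisons. With the correlation estimated for each list, no call held in any comparison. That variant tests each list on the 3 residual degrees of freedom, so hardly any list could pass it. Calls were lost even where the estimated correlation lay below the preset, as for ribosomal proteins (0.0061). It therefore does not tell sound list calls from unsound ones. For other called lists the estimate lay above the preset, as for G2/M and mitosis (0.126), 2-cell-like transcripts (0.141) and uterine epithelium (0.208). The preset p-values of such lists may be too small. The rule for genes named in the text was also fixed then: the 10 largest rises and 10 largest falls past the threshold with no overlap between arrays, leaving out predicted genes, numbered pseudogenes, microRNAs, snoRNAs and olfactory and vomeronasal receptors, the members with the smallest p of each list (4 where it passed, 2 otherwise), and let-7, Myc, mTOR, Lin28, Hmga2 and Odc1 genes. Further members of the 2-cell-like list, the genes opposite in direction, genes changed in both comparisons, Dppa3, Snord42b, Rplp0, Rpl17 and the marker genes given for other cell types were named after their values were seen.

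For agreement between both changes, which share the D4-act-7g arrays, 100 data sets of unchanged groups were simulated from each gene's mean and moderated variance, scaled to each group's spread. The gene and list tests were tested on simulated data of 14020 genes with 200 changed. For Dor-7g versus D4-act-7g, 22.0% of genes changed by 1 log2 unit, 76.0% of those changed by 2 and 100% of those changed by 3 were recovered, with 20 unchanged genes called. For DOX-7g versus D4-act-7g these were 14.0%, 90.0% and 98.0% with 5 called, and for DOX-7g versus Dor-7g 18.0%, 90.0% and 100% with 21 called. A list of 69 genes shifted by -0.3 was recovered in each comparison, and 1 other list was called in Dor-7g versus D4-act-7g. The simulated genes varied independently of each other, whereas the estimated correlation within the G2/M and mitosis list was 0.126. The simulation could therefore not show false list calls that arise from genes moving together. Changes near 1 log2 unit were thus mostly missed, and more unchanged genes were called in both comparisons with Dor-7g than in the other.

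Alternatives covered normalization, filters, the variance model, array weights, the probeset rule, a replicate block, the arrays in the fit, thresholds, other list tests and leaving out each array. Replicate numbers did not pair the samples. The mitochondrially encoded list had no matched gene, and the let-7 family and Y-linked lists were too small to test.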

Results

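Gene expression was measured on 6 Mouse Gene ST arrays, each made from the RNA of 10 blastocysts of let7g-transgenic mice. Diapause is the state in which a blastocyst stops growing before implantation and stays viable, and let-7 is a microRNA family whose role in that state the study addressed. The 3 groups held 2 arrays each: blastocysts activated on day 4 (D4-act-7g), blastocysts dormant in vivo on day 7 (Dor-7g), and blastocysts made dormant in vitro by DOX-induced let-7 on day 7 (DOX-7g). DOX-7g differed from D4-act-7g in day, culture and exposure to DOX as well as in let-7 induction. The 3 groups cannot separate these. Dor-7g differed from D4-act-7g in day as well as in dormancy, and those cannot be separated either. Nothing in the labels says that the 2 arrays of a group came from separate mice or pools, so the p-values of single genes below measure only the spread between these arrays. Camera's p-values set a list's genes against the other genes, which are not replicates, and measure no spread between mice or pools either. The number of arrays limits the precision of every value.

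The median log2 signal over all probesets was 4.87 on Dor-7g replicate 1 and lay between 4.62 and 4.67 on the other 5 arrays. Dor-7g replicate 1 correlated with the other arrays at Pearson's r of 0.899 to 0.919 across probesets, which are not independent replicates. D4-act-7g replicates 1 and 2 correlated at 0.978, and DOX-7g replicates 1 and 2 at 0.969. The median absolute difference between the 2 arrays of a group was 0.17 log2 units in D4-act-7g, 0.36 in Dor-7g and 0.20 in DOX-7g. The first principal component held 41.4% of the variance and placed Dor-7g replicate 1 at 76.4, with Dor-7g replicate 2 at 16.6.

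**Figure D1:**
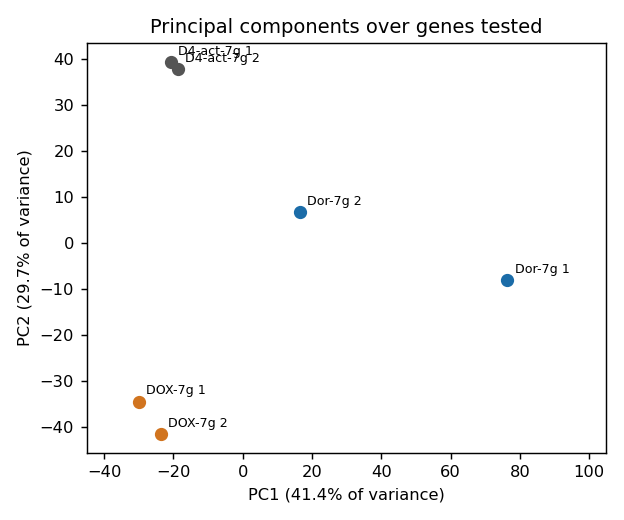
Scores of the 6 arrays on the first 2 principal components of the 14020 genes tested, in log2 units, one point per array, coloured by group. Dor-7g replicate 1 sits at 76.4 on the first component, and the second component places the D4-act-7g arrays at 37.8 and 39.3 and the DOX-7g arrays at -34.4 and -41.4.

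Dor-7g was compared with D4-act-7g to ask which transcripts differ between blastocysts dormant in vivo on day 7 and blastocysts activated on day 4. Nr0b1, a nuclear receptor of pluripotent cells, rose from 5.56 ± 0.65 to 11.77 ± 0.18 log2 units (SD, n = 2 arrays each), a change of 6.21 ± 0.39 (SE; limma, adjusted p = 0.0046). Other large rises were those of the calcium-binding protein genes S100g (5.46 ± 0.60) and S100a1 (4.58 ± 0.29), the ubiquitin-like gene Ubd (4.57 ± 0.35), the homeobox gene Rhox6 (4.04 ± 0.52) and Cox8b (4.30 ± 0.56). The small structural RNAs Rnu3a (6.78 ± 0.63), Rn7sk (6.13 ± 0.49), Scarna17 (5.08 ± 0.26) and n-R5s136 (4.16 ± 0.41) rose too. The largest falls among named genes were those of BC048679 (-7.27 ± 0.37), the histone gene H2bc12 (-6.66 ± 0.24), Wfdc15a (-6.28 ± 0.71), the metallothionein gene Mt4 (-6.09 ± 0.55) and Ly6f (-5.75 ± 0.37). H2bc12 went from 10.42 ± 0.34 in D4-act-7g to 3.76 ± 0.25 in Dor-7g (SD, n = 2 each), a level below the array median.

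The cell division lists had medians below 0 in Dor-7g. Of 52 measured genes of G2/M and mitosis, 4 fell and none rose over all genes tested, and 21 passed when adjusted over the list alone. Those 4 were Birc5 (-3.42 ± 0.31), a chromosomal passenger protein, Mad2l1 (-2.58 ± 0.28), of the spindle checkpoint, Spc24 (-1.93 ± 0.24), of the kinetochore, and the kinesin Kif22 (-1.60 ± 0.19). The list's median change was -0.60, and camera in limma with its preset correlation gave an adjusted p = 4.8e-15 (adjusted p = 0.331 with an estimated correlation). Of 53 DNA replication genes, Rrm2 (-2.05 ± 0.22), a ribonucleotide reductase subunit, and the thymidine kinase Tk1 (-1.93 ± 0.24) fell, and 4 passed when adjusted over the list alone. That list's median was -0.28 (limma camera, adjusted p = 2.4e-06; adjusted p = 0.331 with an estimated correlation).

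The lists of protein synthesis genes also had medians below 0, with few single genes past the threshold. Of 59 cytosolic ribosomal protein genes, Rpl34 (-2.80 ± 0.27), Rpl26 (-1.46 ± 0.16), Rps29 (-2.07 ± 0.24) and Rps16 (-3.15 ± 0.41) fell, and 6 passed when adjusted over the list alone, with a list median of -0.12 (limma camera, adjusted p = 1.4e-04; adjusted p = 0.331 with an estimated correlation). Of 52 translation factors and aminoacyl-tRNA synthetases none passed over all genes, and the median was -0.31 (limma camera, adjusted p = 2.3e-05; adjusted p = 0.331 with an estimated correlation). Of that list 2 passed when adjusted over the list alone, in opposite directions: Eif5 was lower (-1.36 ± 0.25) and Eif4a1 higher by its brightest probeset (3.66 ± 0.65), whose second probeset was at -0.34. The 66 ribosome biogenesis genes had a median of -0.14 with no single gene past either adjustment (limma camera, adjusted p = 0.0071; adjusted p = 0.348 with an estimated correlation). The 44 Myc targets had a median of -0.15 with no single gene past either adjustment (limma camera, adjusted p = 0.0471; adjusted p = 0.331 with an estimated correlation). The call for Myc targets was lost without D4-act-7g replicate 1, Dor-7g replicate 1 or either DOX-7g array, and that for ribosome biogenesis without D4-act-7g replicate 1; a second quantile normalization ended both. Without Dor-7g replicate 2 their medians were -0.09 and -0.09. On Dor-7g replicate 1 the brightest 10% of genes lay a median of 0.22 below replicate 2 and the dimmest 10% a median of 0.25 above it. Rplp0 stood at 6.46 and 11.58 and Rpl17 at 5.69 and 10.08 on Dor-7g replicates 1 and 2, against 11.99 and 11.76 and 11.34 and 10.48 in D4-act-7g. The list medians on replicates 1 and 2 were -0.11 and -0.09 for ribosomal proteins and -0.39 and -0.26 for translation factors, and these 2 calls held without Dor-7g replicate 1 and after the second normalization.

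Of 23 oxidative stress genes Gclm, a subunit of the glutathione-making ligase, fell (-2.03 ± 0.28), 1 passed when adjusted over the list alone, and the median was -0.13 (limma camera, adjusted p = 0.0172; adjusted p = 0.331 with an estimated correlation). The 12 heat shock genes had a median of -0.48, with none past the threshold over all genes and 2 when adjusted over the list alone (limma camera, adjusted p = 0.0241; adjusted p = 0.331 with an estimated correlation). The 11 oocyte and maternal genes had a median of -0.66, with none past over all genes and 5 when adjusted over the list alone (limma camera, adjusted p = 0.0109; adjusted p = 0.331 with an estimated correlation). The 9 trophoblast giant cell genes had a median of 0.32, with none past over all genes and 1 when adjusted over the list alone (limma camera, adjusted p = 0.0241; adjusted p = 0.331 with an estimated correlation). Leaving out either Dor-7g array ended the calls for the oocyte and trophoblast giant cell lists, leaving out D4-act-7g replicate 1 those for the trophoblast giant cell, oxidative stress and heat shock lists, and leaving out Dor-7g replicate 2 that for heat shock. A second quantile normalization ended the calls for oxidative stress, heat shock and trophoblast giant cells. Without Dor-7g replicates 1 and 2 the medians were 0.16 and 0.49 for trophoblast giant cells and -0.22 and -0.20 for oxidative stress, and without replicate 1 that of the oocyte list was -0.30. On Dor-7g replicate 1 the medians of the uterine epithelium, uterine stroma and blood lists lay 0.29, 0.32 and 0.16 above the D4-act-7g mean, against 0.05, 0.06 and 0.05 on Dor-7g replicate 2. The median of all probesets was itself higher on replicate 1 (4.87) than on the D4-act-7g arrays (4.64 and 4.65). After a second quantile normalization the lists lay a median of 0.10, 0.10 and 0.23 higher on replicate 1 than on replicate 2. None of these 3 lists passed in this comparison (limma camera, adjusted p = 0.0619, 0.219 and 0.34).

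In all, 138 of 14020 genes passed limma's adjusted p threshold of 0.05 between Dor-7g and D4-act-7g, 34 higher and 104 lower, and the median change of all genes was 0.06. The count was 265 without Dor-7g replicate 1 (110 higher and 155 lower), 1172 without Dor-7g replicate 2 (274 and 898), 15 and 11 without D4-act-7g replicates 1 and 2, and 86 without either DOX-7g array. Centring each array on its median gave 27 higher and 128 lower. Whichever array was left out, 11 of the 138 genes still passed, among them Nr0b1, S100a1, Scarna17, BC048679 and H2bc12. In simulated arrays with the wider spread of Dor-7g, 20 unchanged genes were called beside 200 changed ones in this comparison.

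DOX-7g was compared with D4-act-7g to ask what differs in blastocysts made dormant by let-7 in vitro. Transcripts of the 2-cell-like state, a state of early-embryo gene expression, were far higher: 9 of 13 measured genes rose, both over all genes and adjusted over the list alone, and the median change was 4.6. Gm4340 rose by 7.20 ± 0.20, Usp17lc by 8.03 ± 0.23, Zscan4a by 6.21 ± 0.28 and Tcstv3 by 6.25 ± 0.58 log2 units (SE, n = 2 each). Zscan4a stood at 12.46 and 12.45 on the DOX-7g arrays, against 6.10 and 6.40 on the D4-act-7g arrays. Usp17la, Usp17ld, Usp17le and Zfp352 did not pass, with changes of 0.14, 0.04, 1.04 and 1.02. limma's camera gave the list an adjusted p = 9.8e-21 (adjusted p = 0.331 with an estimated correlation). In Dor-7g against D4-act-7g the list had a median of 0.00, with Usp17lc lower (-1.71 ± 0.23), and did not pass (limma camera, adjusted p = 0.722). That fall of Usp17lc lay between 2 dim levels, with means of 4.51 in D4-act-7g and 2.80 in Dor-7g. These genes and the Pramel and Tdpoz families have near-identical copies, so which copy was measured is uncertain.

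Outside the 2-cell-like list, AF067061 rose from 3.14 ± 0.03 to 13.12 ± 0.01 log2 units (SD, n = 2 each; limma, adjusted p = 6.0e-05), and other large rises were those of Tdpoz9 (7.21 ± 0.99), Pramel19 (7.17 ± 0.29), Pramel16 (7.11 ± 0.19), Rn7sk (6.99 ± 0.49), Pramel17 (6.47 ± 0.59), D13Ertd608e (6.43 ± 0.68) and Rnu3a (6.37 ± 0.63). Tmed10 rose by 6.29 on its brightest probeset, whereas its 2 other probesets were at -1.04 and -1.0. The arginase gene Arg2 rose by 3.94 ± 0.32, the p53 target Phlda3 by 2.18 ± 0.18 and the antiproliferative gene Btg2 by 2.22 ± 0.30. Efcab10 (-5.58 ± 0.20), Krtdap (-4.73 ± 0.57), Lhfpl5 (-4.05 ± 0.19), the hormone gene Oxt (-3.35 ± 0.36) and Crygs (-3.29 ± 0.26) fell.

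The cell division lists had medians below 0 here as well, but neither passed limma's fry, which compares a list with no other genes. fry gave an adjusted p = 0.0791 for G2/M and mitosis and 0.0628 for DNA replication. In Dor-7g versus D4-act-7g both lists had passed fry (adjusted p = 0.0362 each). Of 52 G2/M and mitosis genes Birc5 fell (-2.18 ± 0.31), 4 passed when adjusted over the list alone, and the median was -0.38 (limma camera, adjusted p = 1.9e-06; adjusted p = 0.348 with an estimated correlation). That median was -0.53 on DOX-7g replicate 1 and -0.20 on replicate 2, and the call held without either. Of 53 DNA replication genes none passed over all genes and 1 when adjusted over the list alone, with a median of -0.33 (limma camera, adjusted p = 7.9e-06; adjusted p = 0.331 with an estimated correlation). The ribosome biogenesis list had a median of -0.15 with no gene past either adjustment (limma camera, adjusted p = 0.0352; adjusted p = 0.412 with an estimated correlation), a call lost without D4-act-7g replicate 1 or either DOX-7g array and after a second quantile normalization. Of 27 naive pluripotency and epiblast genes Dppa2 fell (-2.17 ± 0.20), Dppa3 was also lower (-1.10 ± 0.20) and Nr0b1 higher (2.09 ± 0.39) when adjusted over the list alone, and the median was -0.29 (limma camera, adjusted p = 0.0187; adjusted p = 0.331 with an estimated correlation). That call was lost without D4-act-7g replicate 1 or DOX-7g replicate 2. The oocyte and maternal list had a median of -0.49, with no gene past over all genes and 3 when adjusted over the list alone (limma camera, adjusted p = 0.00909; adjusted p = 0.331 with an estimated correlation).

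Of 26 integrated stress response genes none rose over all genes and 2 passed when adjusted over the list alone, with a median of 0.15 (limma camera, adjusted p = 0.0071; adjusted p = 0.331 with an estimated correlation). The 15 cholesterol synthesis genes had a median of 0.37 with no gene past either adjustment (limma camera, adjusted p = 0.0366; adjusted p = 0.331 with an estimated correlation), a call lost without D4-act-7g replicate 2 (median 0.17) or DOX-7g replicate 1 and after a second quantile normalization; without DOX-7g replicate 2 the median was 0.15. Of 13 blood and immune markers S100a9 (5.00 ± 0.26) and Ly6g (3.54 ± 0.25), both neutrophil genes, rose, and 3 passed when adjusted over the list alone. The list's median was 0.11 (0.07 without DOX-7g replicate 2) and its mean 1.18 (limma camera, adjusted p = 0.0071; adjusted p = 0.331 with an estimated correlation). The 13 uterine epithelium markers had a median of 0.10, with none past over all genes and 1 when adjusted over the list alone (limma camera, adjusted p = 0.0365; adjusted p = 0.546 with an estimated correlation), and that call was lost without either D4-act-7g array, either Dor-7g array or DOX-7g replicate 2. Its median was 0.20 and 0.16 without D4-act-7g replicates 1 and 2 and 0.21 without DOX-7g replicate 1.

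**Figure D2:**
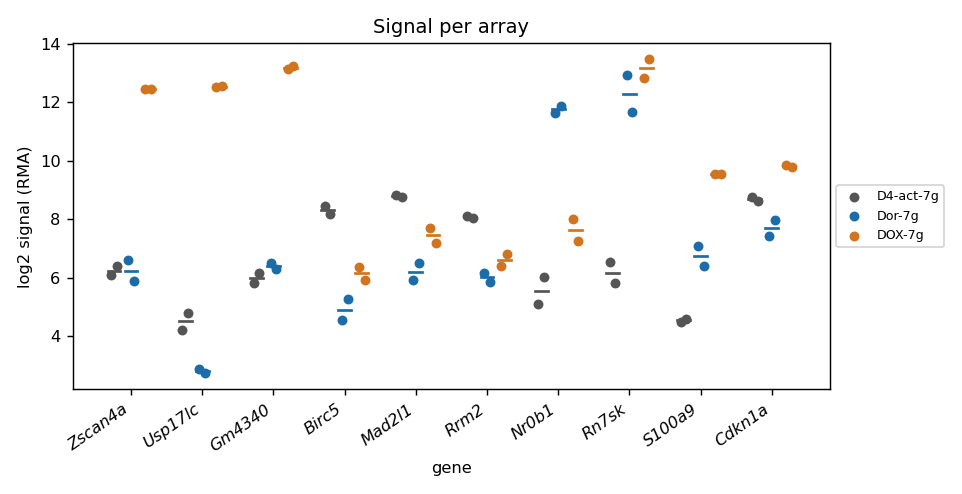
Log2 signal (RMA) of 10 genes on each array, 2 points per group with a bar at their mean. Usp17lc, Zscan4a and Gm4340 have DOX-7g means of 12.54, 12.46 and 13.18, above both other groups, and Birc5 lies lower in both day-7 groups than in D4-act-7g.

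In all, 134 of 14020 genes passed limma's adjusted p threshold of 0.05 between DOX-7g and D4-act-7g, 99 higher and 35 lower, and the median change of all genes was -0.05. The count was 296 without either Dor-7g array (185 higher and 111 lower), which here serve only to estimate the spread, 461 with array weights (260 and 201), 47 and 43 without D4-act-7g replicates 1 and 2, and 67 and 46 without DOX-7g replicates 1 and 2. Whichever array was left out, 31 of the 134 genes still passed, among them Zscan4a, Zscan4e, Usp17lc, Gm4340, AF067061, S100a9, Rn7sk and Efcab10.

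DOX-7g was set against Dor-7g to test whether both kinds of dormant blastocyst differ. The 2-cell-like transcripts were higher in DOX-7g, with 9 of 13 genes past the threshold both over all genes and adjusted over the list alone, and a median of 4.86 (limma camera, adjusted p = 7.0e-18; adjusted p = 0.331 with an estimated correlation). Usp17lc was higher by 9.74 ± 0.23, Gm4340 by 6.78 ± 0.20 and Zscan4e by 4.86 ± 0.23. The heat-inducible chaperone gene Hspa1b was higher by 5.26 ± 0.51, Arg2 by 4.44 ± 0.32, the cell cycle inhibitor Cdkn1a by 2.11 ± 0.24, Phlda3 by 1.99 ± 0.18 and Socs1, an inhibitor of cytokine signalling, by 1.45 ± 0.18. Lower in DOX-7g were Efcab10 (-4.84 ± 0.20), Cox8b (-4.23 ± 0.56), Nr0b1 (-4.13 ± 0.39), Tma16 (-3.77 ± 0.51), Ubd (-3.28 ± 0.35) and the protease inhibitor gene Timp1 (-1.41 ± 0.20). Acss1 was lower by its brightest probeset (-2.78) but not by the other (-0.10).

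The ribosomal protein, translation factor and G2/M lists had medians above 0 in DOX-7g against Dor-7g, with at most 1 gene of each past the threshold over all genes. Those of ribosome biogenesis and Myc targets were -0.03 and -0.04 and did not pass (limma camera, adjusted p = 0.423 and 0.871). limma's fry passed the ribosomal protein list (adjusted p = 0.0441) but neither translation factors nor G2/M (adjusted p = 0.0966 and 0.146). The ribosomal protein list had a median of 0.17, with Rpl34 higher (1.92 ± 0.27) and 1 gene past when adjusted over the list alone (limma camera, adjusted p = 1.9e-06; adjusted p = 0.331 with an estimated correlation). The translation factor list had a median of 0.23, with the elongation factor gene Eef2 higher (1.26 ± 0.17) and 2 past when adjusted over the list alone (limma camera, adjusted p = 1.4e-05; adjusted p = 0.331 with an estimated correlation). The G2/M list had a median of 0.25 and no gene past either adjustment (limma camera, adjusted p = 1.9e-06; adjusted p = 0.348 with an estimated correlation). The heat shock list had a median of 0.23 and 2 genes past when adjusted over the list alone (limma camera, adjusted p = 0.0136; adjusted p = 0.331 with an estimated correlation), a call lost without Dor-7g replicate 2. The 69 nuclear oxidative phosphorylation genes had a median of 0.07 (limma camera, adjusted p = 0.00518; adjusted p = 0.331 with an estimated correlation), with none past either adjustment, and the call was lost without Dor-7g replicate 1. Cholesterol synthesis genes had a median of 0.18, with none past over all genes and 1 when adjusted over the list alone (limma camera, adjusted p = 0.0365; adjusted p = 0.331 with an estimated correlation), a call lost without D4-act-7g replicate 1, either Dor-7g array or DOX-7g replicate 1. A second quantile normalization ended the calls for heat shock, oxidative phosphorylation and cholesterol synthesis. Without Dor-7g replicate 1 the medians were 0.11 for ribosomal proteins and 0.13 for translation factors, and without replicate 2 they were 0.43 for translation factors and 0.11 for cholesterol synthesis. Without DOX-7g replicates 1 and 2 they were 0.37 and 0.10 for heat shock and 0.36 and 0.33 for cholesterol synthesis, and without replicate 2 that of G2/M was 0.16.

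In all, 163 of 14020 genes passed limma's adjusted p threshold of 0.05 between DOX-7g and Dor-7g, 146 higher in DOX-7g and 17 lower. The median difference of all genes was -0.11. Centring each array on its median moved it by 0.13, and that of Dor-7g versus D4-act-7g by -0.13, so list medians of that size depend on the scale, while camera compares a list with the other genes. The count was 218 without Dor-7g replicate 1 (143 higher and 75 lower), 880 without Dor-7g replicate 2 (710 and 170), 86 without either D4-act-7g array, and 89 and 67 without DOX-7g replicates 1 and 2. Whichever array was left out, 52 of the 163 genes still passed.

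**Figure D3:**
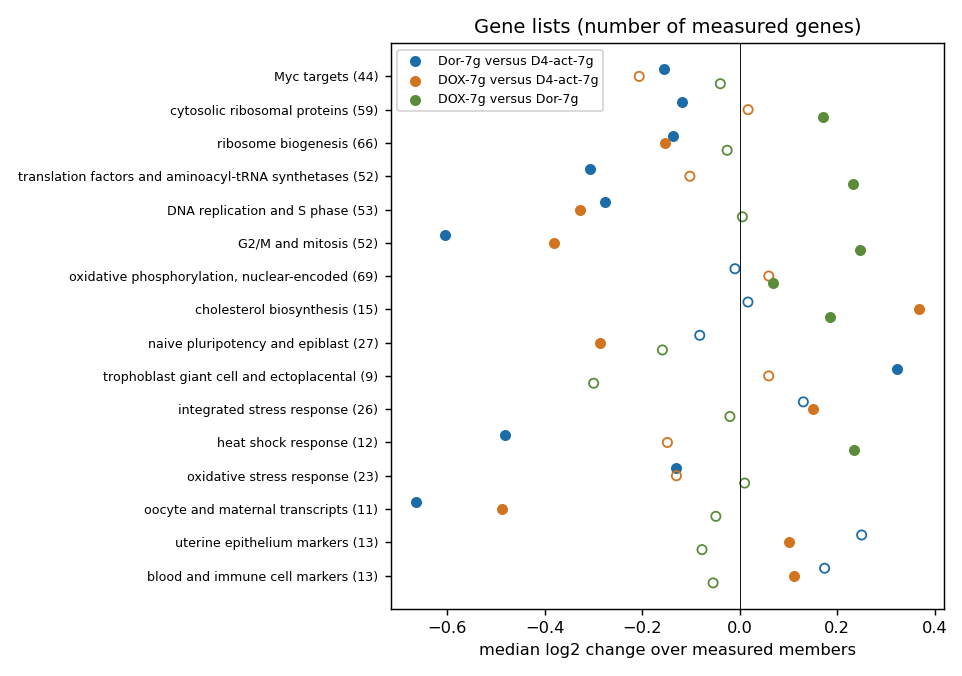
Median log2 change over the measured members of each gene list, one row per list, for the 3 comparisons; filled circles passed camera at an adjusted p of 0.05 and open circles did not. The 2-cell-like list, at 4.6 and 4.86 in the DOX-7g comparisons, is off this scale and not drawn, and G2/M and mitosis lies at -0.60 in Dor-7g and -0.38 in DOX-7g against D4-act-7g.

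The changes of both dormant groups from D4-act-7g were compared across genes. Both dormant groups are from day 7 and D4-act-7g is from day 4, so shared changes may come from day or from dormancy. S100g (5.46 in Dor-7g and 5.13 in DOX-7g), S100a1 (4.58 and 3.02), Rhox6 (4.04 and 5.58), S100a9 (2.21 and 5.00), Rn7sk and Scarna17 rose in both. Birc5 (-3.42 and -2.18), Dppa2 (-3.06 and -2.17), Gclm (-2.03 and -2.14), Oxt (-3.45 and -3.35) and Krtdap (-4.89 and -4.73) fell in both. Uchl1, also lower in both by its brightest probeset (-4.05 and -2.77), has a second probeset at 0.32 and -0.12. In total 18 genes rose in both and 23 fell in both, where independent lists, which leave out the shared D4-act-7g arrays, would share 0.24 and 0.26. Unchanged groups simulated against the same D4-act-7g arrays gave at most 5 calls in Dor-7g and 0 in DOX-7g, so their shared count of 0 was fixed by the lack of calls and is no yardstick for these counts. The genes Cbr2, Nat8f2, Gm20234, B020031M17Rik and Usp17lc, the last with dim means in D4-act-7g (4.51) and Dor-7g (2.80), went in opposite directions. Tmed10 did so by its brightest probeset (-1.98 and 6.29) but not by its 2 others (-2.47 and -1.04, -1.28 and -1.0).

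Across the 14020 genes, which are not independent replicates, the changes correlated at Pearson's r of 0.429 and Spearman's rho of 0.511, against simulated means of 0.277 and 0.256. The covariance was 0.192 against a simulated 0.0244. The simulated changes shared the D4-act-7g arrays too, so noise of the size seen between those arrays is already in the simulated values. A deviation common to both D4-act-7g arrays is not, and part of the excess may come from it. Those arrays are too few to be split into parts of 2. The count of 41 genes changed the same way was 79 and 110 without Dor-7g replicates 1 and 2, 5 and 3 without D4-act-7g replicates 1 and 2, and 15 and 7 without DOX-7g replicates 1 and 2.

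**Figure D4:**
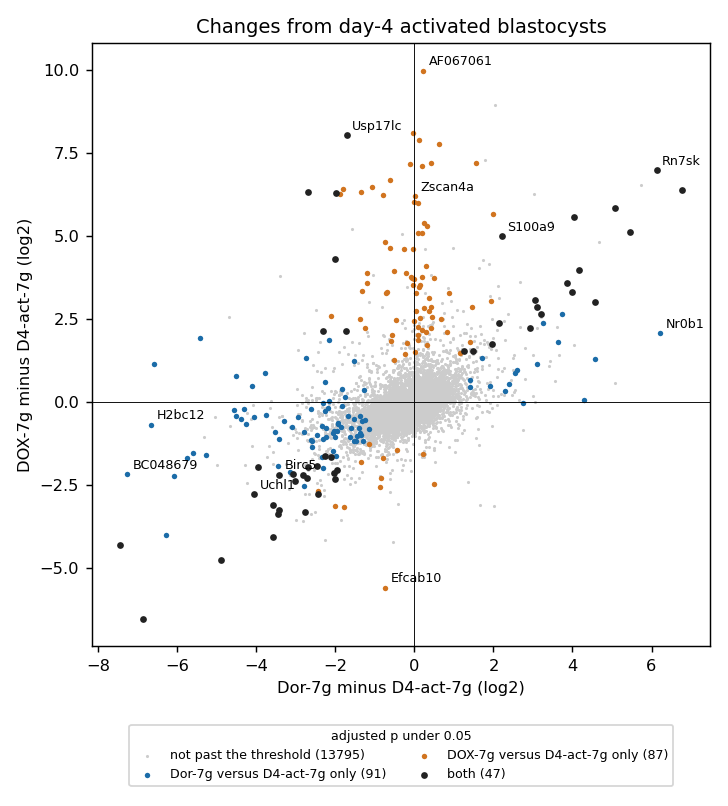
Log2 change of each of the 14020 genes in Dor-7g (horizontal) and DOX-7g (vertical) from D4-act-7g, one point per gene, coloured by the comparison in which it passed limma's adjusted p of 0.05. The 47 genes past the threshold in both comparisons are in black, 41 of them changed the same way in both, and the 2-cell-like genes Zscan4a and Usp17lc lie high on the vertical axis.

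The let-7 genes themselves were mostly dim. Mirlet7a-1 and Mirlet7a-2 were the members bright enough to test: Mirlet7a-1 differed by -0.25 ± 0.33 in Dor-7g and 0.11 ± 0.33 in DOX-7g from D4-act-7g, and Mirlet7a-2 by 0.54 ± 0.20 and -0.63 ± 0.20, none past limma's threshold (adjusted p = 0.751, 0.977, 0.305 and 0.311). The mean of Mirlet7a-2 was dim in D4-act-7g (4.37) and DOX-7g (3.74), so its DOX-7g difference lies between 2 dim levels. Mirlet7g, the family member named in the transgene, was dim, and a probeset on a precursor gene does not measure mature let-7. Of 32 measured let-7 targets Rrm2 fell in Dor-7g. When adjusted over the list alone, Rrm2 was also lower in DOX-7g (-1.47 ± 0.22) and Cdc34 lower in Dor-7g (-1.04 ± 0.18). The list had medians of -0.08 in Dor-7g and -0.14 in DOX-7g against D4-act-7g and passed in neither (limma camera, adjusted p = 0.11 and 0.287). The pluripotency factor Lin28a differed by 0.02 ± 0.19 and -0.23 ± 0.19, Hmga2 by -0.13 ± 0.20 and -0.37 ± 0.20, and Lin28b was dim.

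Myc differed by -0.10 ± 0.20 in Dor-7g and -0.16 ± 0.20 in DOX-7g, Mycn by 0.55 ± 0.27 and 0.20 ± 0.27, and Odc1, the polyamine synthesis enzyme, by -0.25 ± 0.23 and -0.95 ± 0.23, none past limma's threshold. The Myc target list had medians of -0.15 in Dor-7g and -0.21 in DOX-7g against D4-act-7g, and passed only in Dor-7g (limma camera, adjusted p = 0.0471 and 0.0561). Mtor differed by -0.17 ± 0.19 and -0.15 ± 0.19, Rptor by 0.21 ± 0.20 and 0.08 ± 0.20, and Rictor by -0.09 ± 0.16 and 0.10 ± 0.16. Of 40 mTOR components and regulators Castor1, an arginine sensor, fell in Dor-7g (-1.62 ± 0.20), and limma's camera did not pass the list in either comparison (adjusted p = 0.954 and 0.949). fry, which asks whether the genes of a list move one way on balance and compares it with no other genes, gave an adjusted p = 0.0073 in DOX-7g against D4-act-7g, with a median of -0.06. The polyamine list did not pass either, with medians of -0.25 and -0.05 (limma camera, adjusted p = 0.053 and 0.885). Its medians on Dor-7g replicates 1 and 2 were -0.05 and -0.23. Within it Atp13a3 fell in Dor-7g (-2.10 ± 0.19) and in DOX-7g (-1.65 ± 0.19), and Arg2 rose in DOX-7g (3.94 ± 0.32). When adjusted over the polyamine list alone, 4 genes passed in DOX-7g, Arg2 higher and 3 lower, Odc1 among them. Over the Myc target list alone, which also holds Odc1, no gene passed in DOX-7g.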

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

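The tests of explanations in this part were chosen after the results were seen. Results are listed here because the change from D4-act-7g differed between the dormant groups in limma's test of DOX-7g against Dor-7g, or because a signal lay in probesets outside the gene tests. That test passed 163 genes. Lists past camera had median differences of 0.17 (ribosomal proteins), 0.23 (translation factors), 0.25 (G2/M and mitosis), 0.067 (oxidative phosphorylation), 0.18 (cholesterol synthesis), 0.23 (heat shock) and 4.86 (2-cell-like transcripts). Genes higher in DOX-7g than in Dor-7g were AF067061 (9.75), Usp17lc (9.74), B020031M17Rik (9.03), Tmed10 (8.27, with other probesets at 1.44 and 0.27), D13Ertd608e (8.23), Pramel17 (7.55), Tdpoz2 (7.37, with a second probeset at 2.93), Pramel19 (7.29), Pramel16 (6.91), Gm20234 (6.32), H2bc12 (5.99), Csta2 (5.29), BC048679 (5.11), Cbr2 (4.46), Guca1a (4.33), Ly6f (4.07), Nat8f2 (3.89) and Mt4 (3.88). Lower were Efcab10 (-4.84), Cox8b (-4.23), Nr0b1 (-4.13) and Ubd (-3.28). Among 7824 bright probesets without a single gene symbol, limma passed 57 in Dor-7g versus D4-act-7g, 120 in DOX-7g versus D4-act-7g and 118 in DOX-7g versus Dor-7g.

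The 2-cell-like transcripts were high on both DOX-7g arrays. A difference of scale left in the deposited values is not a likely cause: array medians were 4.64 and 4.65 in D4-act-7g and 4.62 and 4.66 in DOX-7g. A second quantile normalization left a median of 4.52, but with arrays so alike it could change little and adds nothing to that. Oocytes or unfertilised eggs in the DOX-7g pools stay open: 21 of 25 oocyte-list members were lower in DOX-7g than in D4-act-7g, Khdc3 (8.79 to 7.57) and Ooep (8.58 to 8.37) among them, with a median change of -0.33 (bootstrap SE 0.0832), and Oog1 was higher (1.56, adjusted p = 0.404), but 12 members were dim and 7 among the brightest 25% of probesets in D4-act-7g, where a small share would not show; earlier tests on the 11 bright (-0.49) and 12 dim members (-0.20) had the same limits. Arrested early-cleavage embryos in the DOX-7g pools stay open too, because the trophectoderm list's median of 0.0019 cannot show a small share of such RNA after RMA. Culture in vitro, exposure to DOX and let-7 induction cannot be told apart. The reason is that 0 groups were cultured in vitro without DOX, and no group had DOX without let-7 induction. A response to let-7 remains an untested hypothesis.

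Rn7sk, Rnu3a and Scarna17 were higher in both day-7 groups. A general gain of small non-coding RNA would move the whole class, but the medians over 65 such genes were 7.95e-04 in Dor-7g (bootstrap SE 0.227; 5 rose and Snord42b fell) and 0.33 in DOX-7g (bootstrap SE 0.239; 7 rose and none fell), which argues against a gain of the whole class and leaves a gain of some of them open. Long transcripts filed with that class were left out after a first look at its values. A difference of scale left in the deposited values is not a likely cause, as array medians lay between 4.62 and 4.87. A second quantile normalization left the smaller of the 2 medians of Rn7sk, Rnu3a and Scarna17 at 6.17, but could have changed little. Day, and whatever else both day-7 groups share, was not tested as a biological explanation.

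Dor-7g replicate 1 stood apart from the other arrays. A monotone distortion of its signal alone would keep ranks, yet its highest Spearman's rho with another array was 0.915, below the lowest rho of 0.929 among the other 5. Such a distortion is thus not the only difference, but one with added noise, a narrower range included, stays open. A narrower signal range from weaker labelling or less RNA is a candidate explanation: across genes, the Dor-7g replicate difference correlated with level at -0.287, against 0.0075 and 0.0563 in D4-act-7g and DOX-7g, although a narrower range had been seen before this test. Uterine or blood cells carried along cannot be told apart from it, since after a second quantile normalization the highest of 3 list medians, that of blood, was 0.227 with a bootstrap SE of 0.304, and 12 of 18 stroma, 12 of 21 epithelium and 9 of 17 blood markers were already at or above the array median in D4-act-7g. Among bright or abundant markers, Wfdc2 stood at 10.91 and 10.99, Col1a1 at 6.56 and 6.45, Dcn at 4.22 and 9.29 and Cd68 at 6.90 and 9.19 on Dor-7g replicates 1 and 2, and no biological explanation was tested.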

How the results depend on the processing

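No setting in this part was chosen after the data were seen, but the tolerance for correlations was. No named gene that had passed changed sign under any setting; across such genes and settings 1235 calls held and 310 were lost, and across called lists 361 held and 98 were lost. At an adjusted p under 0.10 the limma count of genes changed, Dor-7g versus D4-act-7g, was 319 and that of genes changed, DOX-7g versus D4-act-7g, was 244. With array weights the 3 comparisons (Dor-7g versus D4-act-7g, DOX-7g versus D4-act-7g, DOX-7g versus Dor-7g) passed 79, 461 and 104 genes, and with only the 4 arrays compared 86, 296 and 86; the wider spread of Dor-7g then enters only its own comparisons. The replicate block passed 82 genes in Dor-7g versus D4-act-7g and 23 changed the same way in both; the numbers share no pairing (correlations of deviations -0.024, -0.011 and -0.137), and the block uses up 1 degree of freedom. Camera with an estimated correlation passed 0, 0 and 0 lists, fry 6 in Dor-7g versus D4-act-7g and 6 in DOX-7g versus D4-act-7g. The former tests each list on 3 residual degrees of freedom, so hardly any list could pass it. A second quantile normalization passed 5 lists rather than 10 in Dor-7g versus D4-act-7g (lost: Myc targets, ribosome biogenesis, oxidative stress, heat shock, trophoblast giant cell) and 4 rather than 7 in DOX-7g versus Dor-7g (lost: oxidative phosphorylation, cholesterol synthesis, heat shock), and no filter 11 in the latter; the cause was not tested. fry turned the direction of the list mTOR components and regulators, DOX-7g versus Dor-7g, whose median is -0.063 (adjusted p = 0.0073); camera ranks it against other genes and fry does not. Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 11 to 1172 genes in Dor-7g versus D4-act-7g, 43 to 296 in DOX-7g versus D4-act-7g, 67 to 880 in DOX-7g versus Dor-7g, 3 to 110 changed the same way, a correlation of 0.339 to 0.480, and 5 to 10, 7 to 10 and 6 to 8 lists, the 5 without D4-act-7g replicate 1. Correlations within 0.0414 of 0.429, a tolerance taken from the range between simulated data sets, were counted as unmoved. Dim probesets limit what can be called.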

Other observations

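All tests in this part were planned, and none weighs an explanation. Lineage lists other than those in the report did not pass limma's camera between Dor-7g and D4-act-7g. The primitive endoderm list had a median of 0.30 over 28 genes (camera, adjusted p = 0.0871). Adjusted over the list alone, 3 of its members passed: Sparc was higher (1.31 ± 0.19), and Cited1 (-1.33 ± 0.23) and Apoa1 were lower. The trophectoderm list had a median of 0.05 over 26 genes (camera, adjusted p = 0.428). Both lists passed limma's fry as higher (adjusted p = 0.0303 and 0.0282). Their medians on Dor-7g replicates 1 and 2 were 0.26 and 0.12 for primitive endoderm and 0.19 and -0.01 for trophectoderm. The formative and primed epiblast list had a median of 0.14 (camera, adjusted p = 0.347) and the imprinted genes 0.23 (camera, adjusted p = 0.299). On Dor-7g replicates 1 and 2 these were 0.37 and 0.01 for formative and primed epiblast and 0.24 and 0.06 for imprinted genes. In the naive pluripotency list Nr0b1 rose while Dppa2 (-3.06) and Dppa3 (-2.31) fell, and the list did not pass (adjusted p = 0.287). The stress gene Nupr1 rose by 3.74 ± 0.45 in Dor-7g, and Socs1 fell by 2.23 ± 0.18.

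Metabolic and signalling lists did not pass in Dor-7g or DOX-7g against D4-act-7g by limma's camera: glycolysis (medians -0.16 and -0.10), TCA cycle (-0.09 and -0.08), fatty acid oxidation (0.07 and -0.12), autophagy and lysosome (-0.02 and -0.13), Wnt (0.17 and 0.04), LIF and STAT3 (0.06 and -0.07), implantation competence (0.08 and -0.04), interferon (0.07 and 0.06), chromatin regulators (0.03 and -0.05), p53 targets (-0.08 and 0.08), cell cycle inhibitors (0.01 and 0.02) and the unfolded protein response (-0.17 and -0.28). Of the genes in these lists, Phlda3 and Btg2 rose in DOX-7g. Some list medians differed between Dor-7g replicates 1 and 2, as for TCA cycle (-0.20 and 0.08) and Wnt (0.31 and 0.03). Others were LIF and STAT3 (0.23 and -0.06) and implantation competence (0.13 and 0.03). In DOX-7g versus Dor-7g fry passed primitive endoderm as lower (median -0.17, adjusted p = 0.0277) and p53 targets as higher (median 0.02, adjusted p = 0.0362), which camera did not (adjusted p = 0.888 and 0.0743). Among lists past camera the median, mean and direction of the test shared a sign. Of the others, median and mean differed in sign for heat shock (-0.15 and 0.53) and ribosomal proteins (0.02 and -0.18) in DOX-7g versus D4-act-7g, for blood markers (-0.05 and 0.89) and oocyte genes (-0.05 and 0.34) in DOX-7g versus Dor-7g, and for further lists with smaller means. The test pointed up while median and mean lay below 0 for translation factors, glycolysis and fatty acid oxidation in DOX-7g versus D4-act-7g and for mTOR and uterine epithelium in DOX-7g versus Dor-7g. The S100a8 values of 10.91 and 10.12 on the DOX-7g arrays compare with 2.81 and 7.18 on the Dor-7g arrays, and its change of 7.30 ± 1.31 did not pass limma's threshold (adjusted p = 0.0949).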
